A study of Mus musculus with 4 samples.

How the data were processed

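Renal gene expression was measured on 4 Affymetrix 3' expression arrays, 1 for each combination of diabetes and surgery. Per the labels' protocols, RNA was extracted from frozen kidney with TriZol, RNA of 4 female mice was pooled in each group, and 100 ng of each pool was labelled with biotin using the 3' IVT Express kit. The deposited table holds linear intensity values for 45101 probe sets, already summarised from single probes. The authors' software and the arrays' background correction are not given in the sources used here. The mean of the deposited intensities without the highest and lowest 2% was 500.003 on each array, so the values had been scaled to a common level before they were deposited.

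The platform annotation used here gave 1 gene symbol for 34945 of the 45037 probe sets that are not controls and several symbols for 932. The remaining 9160 are unnamed here. Symbols were updated through the Entrez gene number in a RefSeq gene table of assembly GRCm38.p6, which held 34741 of the 34945 and changed 0 symbols. Probe sets with several symbols or none were left out, and so were the 64 control probe sets, except where named.

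Intensities were set on the log2(value + 26.4) scale, where 26.4 is the 20th percentile of all values. This offset makes fold changes of dim genes smaller than the ratio of their intensities. The median log2 values of the 4 arrays lay within 0.5 of each other, so no further normalisation was applied. Each of 18193 genes was represented by its probe set with the highest mean. A gene counted as expressed when its mean log2 value reached 7.06, the median over all probe sets, which left 11206 genes. Pearson correlations between arrays across these genes lay between 0.969 and 0.983. Genes are not independent replicates.

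With 1 array per group, a difference between 2 groups has no replicate check and no p-value. Such differences are given as values, with counts of genes at least 2-fold higher or lower. Diabetes was compared in sham and in uninephrectomised mice, and uninephrectomy in nondiabetic and in diabetic mice. The 2 arms of each factor share no array, so each arm checks the other. For each factor an additive model with the other factor as covariate was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a trend in mean expression), and genes passed at a Benjamini-Hochberg adjusted p below 0.05. In limma terms each gene has 1 residual degree of freedom, against 57.9 prior degrees of freedom taken from all genes. The standard error of a gene therefore comes nearly entirely from other genes of like expression, and a gene with a large difference in only 1 arm can pass. The words rose and fell are used only for genes that passed. The mice were pooled, so no value measures the spread between animals.

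The difference between the effects of uninephrectomy, diabetic minus nondiabetic, uses all 4 arrays and 4 coefficients, which leaves no residual. The same contrast is the split of the arrays that follows neither factor (nondiabetic sham with diabetic uninephrectomy against the other 2 arrays), which was fitted with limma with only surgery and again with only diabetes as covariate. The effect of the factor left out then lies in the residual, and the prior degrees of freedom were 5.86 and 6.51.

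Before the data were examined, 33 gene lists were fixed, covering matrix, injury, immune, nephron segment, metabolic, stress and other cell type genes. For lists with at least 5 expressed members, the median log2 difference was ranked among the medians of 10000 random lists of the same size, drawn from expressed genes in the same of 10 bins of mean expression. A list counts as standing apart when it lay above or below 9750 of them. This describes these arrays and does not test the conditions. List members that passed limma were counted over all 11206 genes and adjusted over the list alone.

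Named genes followed a rule fixed before the data were examined: for each factor the 12 highest and 12 lowest genes by the smaller of their 2 arm differences, for the difference of effects the 10 most positive and 10 most negative, for each of the 4 differences between 2 arrays the 3 highest and 3 lowest, and from each list up to 4 members with the largest mean difference of either factor. As a check of the labels, the insulin gene Ins2 and sex-linked genes were looked up. Alternatives were quantile normalisation, median centring, no filter and a stricter filter (75th percentile) on expression, the mean of a gene's probe sets, probe sets counted singly, offsets of 1 and of 72.5 (the 40th percentile), a 1.5-fold threshold, limma without a trend, and an adjusted p below 0.1.

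The limma step was tested on simulated data made from the 11206 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale between diabetic and nondiabetic arrays. It recovered 75% and 100% of them, with 9 unchanged genes among 184 calls and 0 calls for the uninephrectomy factor, where no effect had been put in. The simulated noise was drawn with the standard deviations that limma had fitted. It held no difference between array pairs or between arms. The recovery therefore checks the code and not the calls made on the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.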

Results

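The series asks how the kidney of diabetic mice differs in gene expression from that of nondiabetic mice, and how removal of a kidney, used as an accelerating factor, alters this. OVE26 mice are transgenic FVB mice that become diabetic early in life through a transgene expressed in pancreatic beta cells. Uninephrectomy, the removal of 1 kidney, or a sham operation was done at 2 months of age. Kidneys were taken at 4.5 months, 10 weeks after surgery, following perfusion with buffered saline. The 4 groups were nondiabetic sham, nondiabetic uninephrectomy, diabetic sham and diabetic uninephrectomy mice, each measured on 1 array of RNA pooled from 4 mice. The median array signal was 106.8, 119.3, 115.3 and 107.7 in these groups, in this order. The number of arrays limits the precision of every value below. Xist, transcribed from the inactive X chromosome, had signals between 12775 and 14743, while the highest signal of 3 Y-linked genes was 56.3, so the arrays matched the labels' sex. The insulin gene Ins2 lay below the expression filter, and the transgene itself was not analysed here.

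In kidneys of diabetic mice, genes of tubular injury, extracellular matrix and the cell cycle were higher, and the differences were larger after uninephrectomy than in sham mice. The signal of 3 control probe sets for 18S ribosomal RNA moved in the same order: it was 1.02-fold that of nondiabetic sham mice in nondiabetic uninephrectomy, 1.32-fold in diabetic sham and 1.88-fold in diabetic uninephrectomy mice (geometric means). Lcn2, which encodes the secreted tubular injury marker NGAL, had a signal of 41.7 in nondiabetic sham and 224.5 in diabetic sham mice. After uninephrectomy its signals were 5.7 and 3374. Its mean log2 difference with diabetes was 4.30 ± 0.44 (limma SE, adjusted p = 3.9e-10), made of 1.88 in sham and 6.73 in uninephrectomised mice. Both nondiabetic signals of Lcn2 lie below the expression filter, so the size of its differences is set by the offset (6.73 becomes 8.98 with an offset of 1 and 5.46 with the 40th percentile). Cdkn1a, the cell cycle inhibitor p21, rose by a mean log2 difference of 1.95 ± 0.22 (limma adjusted p = 6.6e-09), and Angptl4, a PPAR target that inhibits lipoprotein lipase, by 1.75 ± 0.18 (limma adjusted p = 3.9e-10). Angptl4 differed more in sham (log2 2.18) than in uninephrectomised mice (1.32), the reverse of Lcn2 and Cdkn1a (1.36 and 2.54).

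Between the diabetic and the nondiabetic sham array 89 genes were at least 2-fold higher and 50 lower, of 11206 expressed genes. Between the uninephrectomised arrays 240 were higher and 116 lower. Of these expressed genes 15 were higher and 6 lower in both arms, against 1.91 and 0.52 for independent lists of the same sizes. In opposite directions 12 differed, against 1.99. As these exceeded their number too, the count of shared genes does not by itself show a common effect of diabetes. Without the expression filter 852 were higher and 442 lower in sham mice, 657 and 900 in uninephrectomised mice, and 78 and 71 in both. In each arm the larger number lay on the array with the higher 20th percentile of signal. Across the expressed genes the 2 arms correlated weakly (Pearson r = 0.16, Spearman rho = 0.10). With limma, 165 genes rose and 82 fell with diabetes, including 20 of the 21 genes at least 2-fold different in both arms. Of these 247 genes, 245 had the same sign in both arms, 110 were at least 1.5-fold different in both, and 62 had arms that differed by 2-fold or more. As limma tests the mean of the 2 arms, the shared signs and the overlap with the 2-fold genes are no independent check. The number passing depended strongly on the settings: it was 0 with limma's prior variance held constant over expression (907 genes at an unadjusted p below 0.05), 5 with the mean of each gene's probe sets 13 without the expression filter and 62 with probe sets counted singly.

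**Figure D1:**
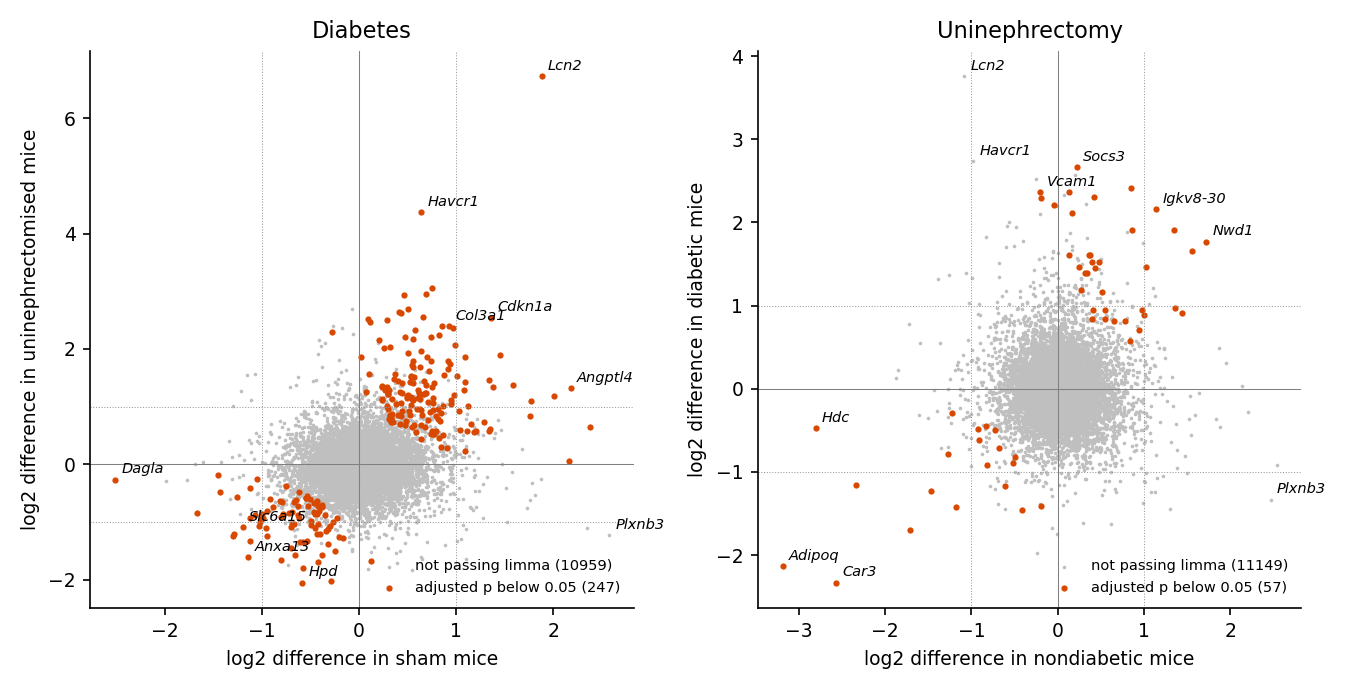
Log2 differences of 11206 expressed genes with diabetes (left panel, sham mice on the x axis and uninephrectomised mice on the y axis) and with uninephrectomy (right panel, nondiabetic mice on the x axis and diabetic mice on the y axis), with orange points for the 247 and 57 genes that passed limma and dotted lines at 2-fold. Lcn2 lies at 1.88 and 6.73 in the left panel and at -1.09 and 3.76 in the right panel, while Car3 and Adipoq lie below -2 in both arms of uninephrectomy.

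The other genes most raised by diabetes in both arms were of several kinds. Aldh1a7, an aldehyde dehydrogenase, rose by a mean of 1.68 ± 0.19 on the log2 scale (limma adjusted p = 2.6e-09), and Utp20, a factor of ribosomal RNA processing, by 1.48 ± 0.18. Mki67, Uhrf1 and Cdc20, all expressed in dividing cells, rose by 1.40, 1.36 and 1.48. The neurotrophin receptor gene Ntrk2 rose by 1.60, the fatty acid hydroxylase gene Cyp4a12a by 1.43, the chemokine gene Ccl8 by 1.25 and the calcium-regulating hormone gene Stc1 by 1.19. All 12 genes chosen for the highest concordant differences and all 12 for the lowest passed limma. This nearly follows from the choice, as limma tests the mean of the same 2 arm differences. Only 2 and 4 of these genes had a further expressed probe set.

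Among genes lower in diabetic kidneys, the transcription factor gene Egr1, an immediate early gene, fell by 1.03 on the log2 scale (SE 0.15, limma adjusted p = 4.7e-06), from signals of 5930 and 6902 in nondiabetic to 2700 and 3601 in diabetic mice. Slc6a15, an amino acid transporter gene, fell by 1.14 and Pigr, the receptor that carries immunoglobulin A across epithelia, fell by 1.09. Anxa13 fell by 1.37 and Corin, which encodes the protease that activates natriuretic peptides, fell by 1.25. Agmat fell by 1.05, Sugct by 1.01, Abcb1a by 1.03, C1qtnf3 by 0.98 and Esm1, an endothelial proteoglycan gene, by 0.96. The predicted genes Gm6958 and 2900052L18Rik fell by 1.27 and 1.23.

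The tubular injury list had 14 expressed members, of which 10 rose and 0 fell with diabetes in limma, and 12 rose adjusted over the list alone. Its median log2 difference was 0.42 in sham and 1.43 in uninephrectomised mice, both above all 10000 random lists. Standing apart was common: of 29 lists with enough members, 14 did so with diabetes in sham and 16 in uninephrectomised mice. Havcr1, the proximal tubule injury marker KIM-1, had signals of 221 and 359 in nondiabetic and diabetic sham mice, and of 98.8 and 2552 after uninephrectomy. Its mean difference of 2.50 ± 0.34 passed limma (adjusted p = 5.7e-07) but came mainly from the uninephrectomised arm (0.64 and 4.36). Cd44 rose by 1.53 (0.99 in sham and 2.07 in uninephrectomised mice).

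Of 31 expressed genes of extracellular matrix and fibrosis, 14 rose and 0 fell in limma (21 rose and 1 fell adjusted over the list alone). The median log2 difference was 0.39 in sham and 0.94 in uninephrectomised mice, both above all 10000 random lists, and 1 and 13 members were at least 2-fold higher. Col3a1, a fibrillar collagen gene, rose by 1.66 ± 0.18 (limma adjusted p = 2.2e-09), with signals of 1122 and 2150 in sham and of 1230 and 6610 in uninephrectomised mice. Lox, which cross-links collagen, rose by 1.36, Col5a2 by 1.35 and Col1a2 by 1.17. Among 10 mesangial, pericyte and smooth muscle markers 3 rose (4 rose and 1 fell adjusted over the list alone), with medians of 0.34 and 0.27 in the 2 arms, above 9988 and 9867 random lists. They were the smooth muscle genes Tagln (1.03) and Acta2 (0.78) and the pericyte gene Rgs5 (0.74).

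Cell cycle genes followed the same order of arms. Of 15 expressed members 7 rose and 0 fell in limma (12 rose adjusted over the list alone), and the medians of 0.56 in sham and 1.36 in uninephrectomised mice lay above all 10000 random lists. Rrm2, a subunit of ribonucleotide reductase, rose by 1.34 ± 0.21 (limma adjusted p = 2.2e-05), and the replication helicase gene Mcm6 by 1.47.

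Metabolic lists moved less, and several had different signs in the 2 arms of diabetes, a difference that follows the same split of the arrays as the spike-in probe sets described at the end. The median of 21 fatty acid oxidation genes and PPARA targets was 0.31 in sham mice, above all 10000 random lists, and -0.14 in uninephrectomised mice, inside the central 95%. In limma 2 rose, Angptl4 and the thioesterase gene Acot2 (0.60), while 5 rose and 1 fell adjusted over the list alone. The median of 14 gluconeogenesis and glucose transport genes was likewise 0.27 in sham mice, above all 10000 random lists, against -0.11 in uninephrectomised mice, and 1 rose by either adjustment, the sugar transporter gene Slc5a10 (0.66). Lipid and sterol synthesis was lower in both arms, with medians of -0.23 and -0.17 over 18 genes, below all but 5 and 198 of the random lists. In limma 2 fell (4 adjusted over the list alone): Srebf1, a master regulator of lipid synthesis, fell by 0.93 (SE 0.16, adjusted p = 0.0001) and the desaturase gene Scd1 by 0.73. Of 16 insulin and FOXO targets only Pdk4, which restrains glucose oxidation, rose (1.31 ± 0.17, limma adjusted p = 3e-07), and 1 rose and 3 fell adjusted over the list alone. Their medians were 0.07 and 0.01. Of 20 antioxidant genes and NRF2 targets 3 rose by either adjustment, namely the metallothionein genes Mt2 (0.93) and Mt1 (0.87) and Srxn1 (0.62). Their median was 0.24 in sham mice, above all 10000 random lists, and 0.05 in uninephrectomised mice.

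The 12 glycolysis genes had medians of 0.17 and 0.22, above 9780 and 9979 random lists, and 0 passed limma (1 rose adjusted over the list alone). The 23 oxidative phosphorylation genes had medians of 0.14 and -0.17, of which the former stood above 9776 random lists, and 0 passed by either adjustment. The 7 expressed NADPH oxidase genes had medians of 0.12 and -0.21, and 0 passed. Among 12 renin-angiotensin and vasoactive genes, angiotensinogen (Agt) rose by 0.74 (1 adjusted over the list alone too), with list medians of 0.02 and -0.07.

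Proximal and distal tubule markers were lower mainly in the uninephrectomised arm of diabetes. The median of 19 proximal tubule markers was 0.03 in sham and -0.40 in uninephrectomised mice, the latter below all 10000 random lists. Slc22a8, an organic anion transporter gene, fell by 0.72 with diabetes (SE 0.17, limma adjusted p = 0.0077) and was the 1 member to pass, against 2 that fell adjusted over the list alone. Of 12 loop of Henle and distal tubule markers, with medians of -0.04 and -0.29 (the latter below all but 14 random lists), Pvalb fell by 0.78, and 5 fell adjusted over the list alone. Of 15 collecting duct markers, with medians of -0.22 (below all but 31) and -0.09, the intercalated cell genes Slc26a4 and Atp6v1b1 fell by 0.85 and 0.65, while the water channel gene Aqp2 rose by 0.80. Adjusted over the list alone 1 rose and 3 fell. Aqp2 was also the 1 gene to rise among 11 osmolyte, polyol and urea handling genes (by either adjustment), which had medians of 0.11 and 0.19, the latter above 9836 random lists and -0.052 under the stricter expression filter. Of 16 podocyte markers Nphs1, which encodes nephrin of the slit diaphragm, fell by 0.93 (SE 0.27, limma adjusted p = 0.044), also the 1 member to fall adjusted over the list alone. The podocyte medians of -0.11 and -0.14 and the medians of 13 endothelial markers, 0.05 and 0.04, lay inside the central 95% of random lists, and 0 endothelial markers passed. Taken over the mean of both arms, the podocyte median of -0.18 lay below all but 23.

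Immune genes differed between the arms of diabetes too. The median of 14 macrophage markers was -0.00 in sham mice and 0.86 in uninephrectomised mice, the latter above all 10000 random lists. In limma 2 rose, the lysozyme gene Lyz2 (1.70 ± 0.23, adjusted p = 6.5e-07) and the endotoxin co-receptor gene Cd14 (from arms of -0.28 and 2.29), and 3 rose adjusted over the list alone. Of 14 cytokine, chemokine and adhesion genes 3 rose (4 adjusted over the list alone), including Ccl2, which attracts monocytes (1.40, from arms of 0.29 and 2.50), and Icam1 (0.78). Ccl2 signals of 76, 75.3 and 98.9 in nondiabetic sham, nondiabetic uninephrectomy and diabetic sham mice lay below the expression filter. The size of its differences therefore depends on the offset. The cytokine list had medians of 0.14 and 0.59, the latter above 9999 random lists. Of 13 complement and coagulation genes 3 rose (6 rose and 1 fell adjusted over the list alone), with medians of 0.10 and 0.63, the latter above all 10000 random lists. The fibrinogen genes Fgg and Fga rose by 1.60 and 0.79, and the complement factor I gene Cfi by 1.18. Of 14 interferon response genes 1 rose by either adjustment, Ifi27l2a (1.01), with medians of -0.03 and 0.47, the latter above 9999. The 12 antigen presentation genes had medians of -0.18 in sham mice, below all but 117 random lists, and 0.12 in uninephrectomised mice, and 0 passed.

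In the single sham comparison of diabetes the highest genes were Plxnb3 (log2 2.58), Serpina6 (2.38) and Lce1h (2.35), and the lowest were Dagla (-2.52), Hif3a (-1.99) and Gpr153 (-1.77). Plxnb3 and Lce1h were lower in the other arm (-1.23 and -1.10). In uninephrectomised mice Lcn2, Havcr1 and Tnfrsf12a, the TWEAK receptor gene (3.06), were highest. The lowest were Hpd, an enzyme of tyrosine breakdown (-2.05), Ang (-2.03) and C130026I21Rik (-1.83). Hpd fell by a mean of 1.32 with diabetes (SE 0.18, limma adjusted p = 6.5e-07).

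**Figure D2:**
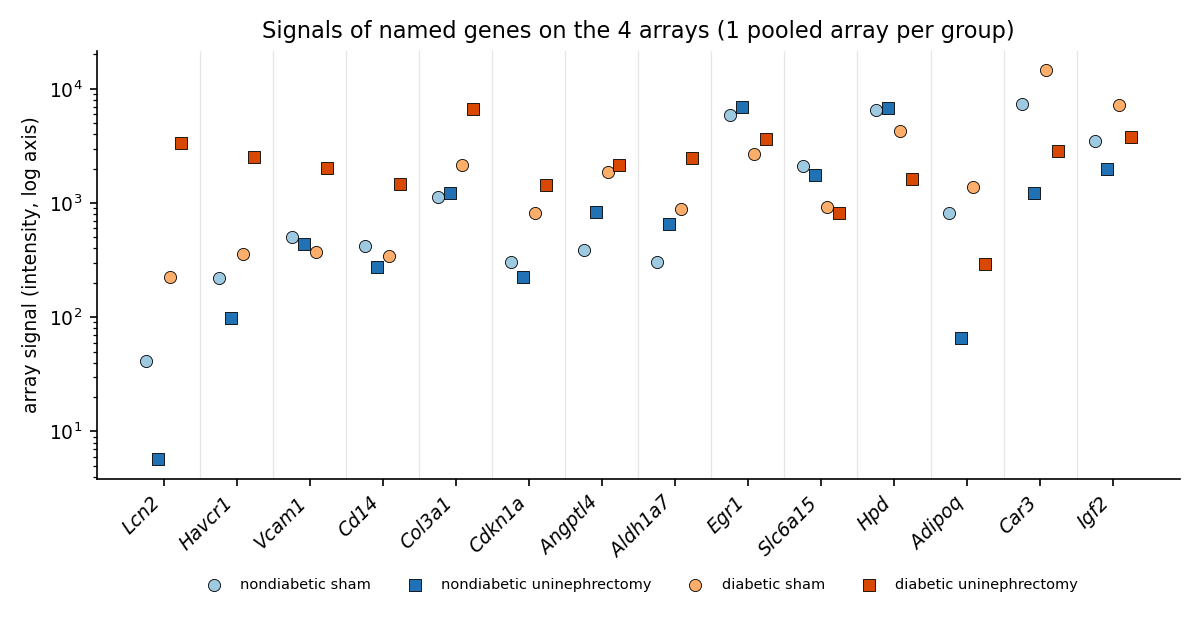
Array signal (intensity, log axis) of 14 named genes, with 1 point per pooled array, circles for sham and squares for uninephrectomised mice, and blue for nondiabetic and orange for diabetic mice. Lcn2 reaches 3374 and Havcr1 2552 on the diabetic uninephrectomy array, and Adipoq is at 66.2 and 293.5 on the uninephrectomy arrays against 817.3 and 1380 on the sham arrays.

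Uninephrectomy alone was compared between sham and operated mice of the same diabetes status. The clearest differences shared by nondiabetic and diabetic mice were in genes of fat cells. Car3, a carbonic anhydrase abundant in adipocytes, fell by 2.45 on the log2 scale (SE 0.15, limma adjusted p = 5.3e-19), with signals of 7398 and 1229 in nondiabetic and of 14558 and 2874 in diabetic mice. Adipoq, which encodes the adipocyte hormone adiponectin, fell by 2.66 (SE 0.24, limma adjusted p = 2.8e-12). Its signal on the nondiabetic uninephrectomy array lay below the expression filter, so the size of its difference there depends on the offset. Of 6 expressed adipose markers these 2 fell, and 4 fell adjusted over the list alone. The list medians of -0.65 in nondiabetic and -0.76 in diabetic mice lay below all 10000 random lists. The same list was higher with diabetes (0.50 in sham and 0.65 in uninephrectomised mice, above 9993 and 9997), where Adipoq, Car3 and Fabp4 rose by 1.26, 1.09 and 1.05 (3 rose and 1 fell adjusted over the list alone).

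In nondiabetic mice 76 genes were at least 2-fold higher and 58 lower after uninephrectomy, and in diabetic mice 166 and 75. Other expressed probe sets of the higher genes had the same sign for 6 of 11 genes in nondiabetic mice (median 0.13) and for 38 of 44 in diabetic mice (median 0.70), and those of the lower genes for 8 of 11 (median -0.28) and 7 of 10 (median -0.63). In both, 8 genes were higher and 6 lower, against 1.13 and 0.39 for independent lists, and 14 went opposite ways, against 1.37. Since genes going opposite ways exceeded their number too, the count of shared genes does not by itself show a common effect of uninephrectomy. Without the expression filter the numbers were 847 and 395 in nondiabetic mice, 577 and 857 in diabetic mice, and 66 and 51 in both. Here too the larger number in each arm lay on the array with the higher 20th percentile of signal. The 2 arms were uncorrelated across the expressed genes (Pearson r = -0.02, Spearman rho = -0.04). With limma 37 genes rose and 20 fell, among them 11 of the 14 shared genes. Of the 57, 54 had the same sign in both arms and 24 had arms that differed by 2-fold or more. As with diabetes, the shared signs are no independent check. Without a trend in limma's prior variance the number was 4, and 594 genes had an unadjusted p below 0.05. The split of the arrays that follows neither factor gave as many under that setting, 596 with diabetes as covariate (361 with surgery). With the trend, 636 genes had an unadjusted p below 0.05 for uninephrectomy in limma. The split that follows neither factor then gave 626 with diabetes as covariate (303 with surgery). The number passing was 2 with the mean of probe sets, 2 without the expression filter, 16 with probe sets counted singly and 115 after quantile normalisation. That scaling also turned the split in nondiabetic mice from 76 higher and 58 lower genes to 63 and 72.

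Among the 12 genes highest after uninephrectomy in both arms 8 passed. Nwd1 rose by 1.75 ± 0.31 (limma adjusted p = 0.00032), Igkv8-30, an immunoglobulin light chain segment, by 1.65 ± 0.21 (limma adjusted p = 3e-07), Il1f6, an interleukin-1 family cytokine gene, by 1.63 and Nacc1 by 1.61. Aldh1a7 rose by 1.24, Zdhhc12 by 1.18, Fgb by 1.16 and Slc16a6 by 0.96. Niban3, Arsi, Ckap2 and Uhrf1 did not pass, at mean differences of 1.37, 1.16, 1.13 and 1.04. Of the 12 lowest 8 passed as well. Apart from Car3 and Adipoq, Thrsp, a lipogenic gene, fell by 1.75, Krtap12-1 by 1.71, Fam160a1 by 1.35 and the sulfate transporter gene Slc13a4 by 1.30. The transporter gene Abcc3 fell by 1.03 and the growth factor gene Igf2 by 0.87. Corin, Zfp595, Rnf225 and Ptprn2 did not pass, at -0.97, -0.98, -0.83 and -0.79.

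**Figure D3:**
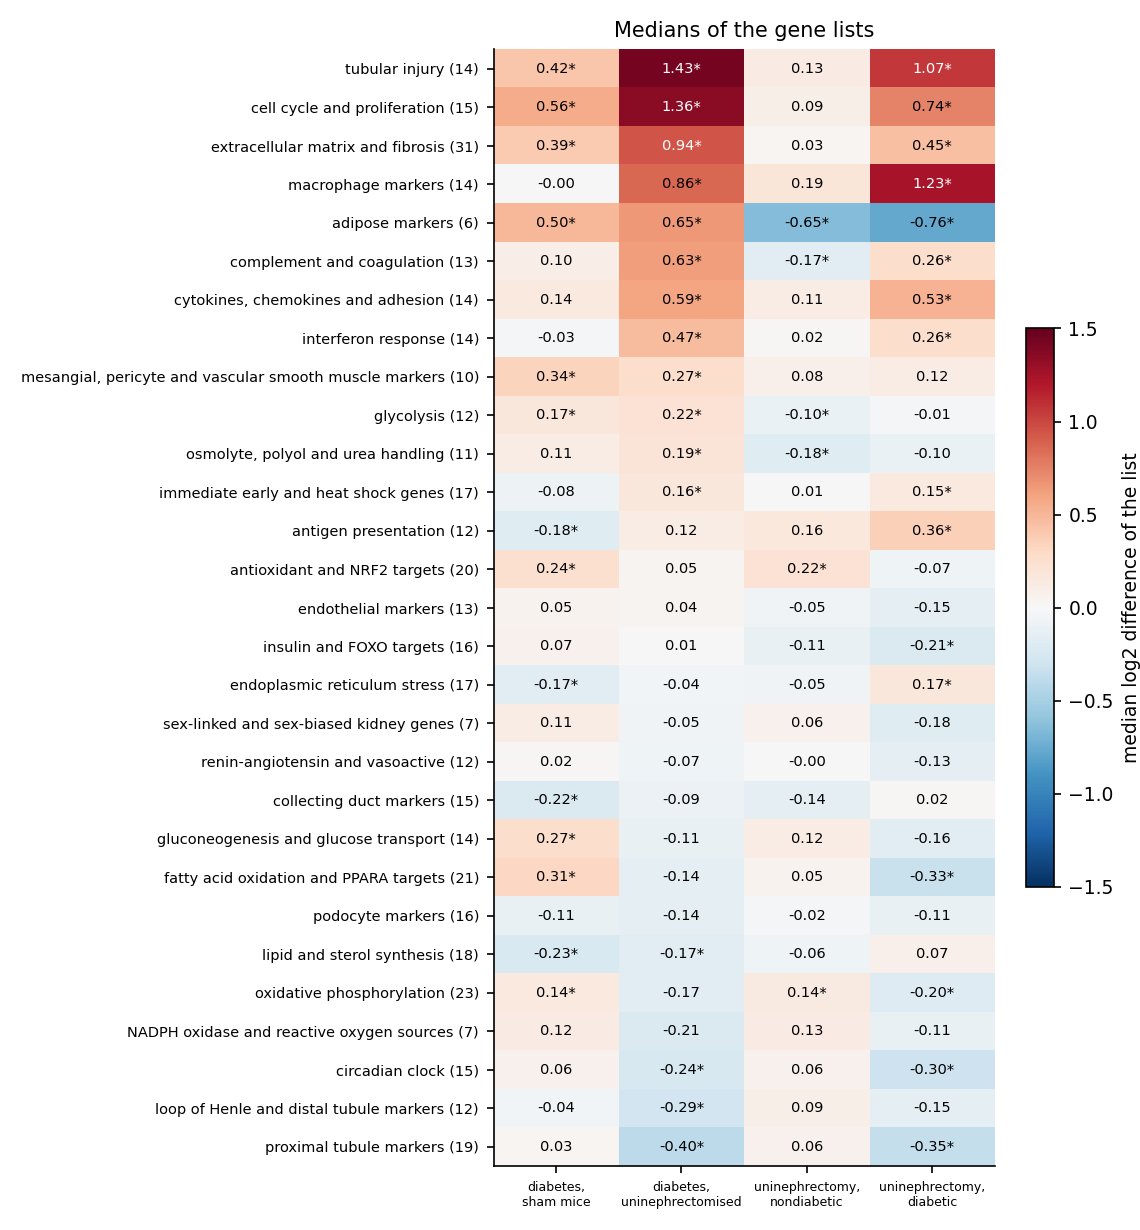
Median log2 difference of each gene list with at least 5 expressed members (number of members in parentheses) in the 4 comparisons between 2 arrays, where an asterisk marks medians above or below more than 9750 of 10000 random lists matched on expression. Tubular injury, cell cycle, matrix and macrophage lists have their highest medians in diabetic uninephrectomised mice, while the adipose list is negative in both comparisons of uninephrectomy (-0.65 and -0.76).

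Inflammatory and injury lists were among the 16 of 29 lists that stood apart after uninephrectomy in diabetic mice, against 6 in nondiabetic mice. The median of the 14 macrophage markers was 0.19 in nondiabetic and 1.23 in diabetic mice, the latter above all 10000 random lists, with 9 members at least 2-fold higher. Lyz2 rose by 1.05 ± 0.23 (limma adjusted p = 0.01), from arms of -0.19 and 2.29, the 1 member to pass against 9 that rose adjusted over the list alone. Tubular injury genes had medians of 0.13 and 1.07 (the latter above all 10000), with 4 that rose and 11 adjusted over the list alone. Among them was Vcam1, an adhesion molecule gene (1.08, from -0.20 and 2.36). The cytokine, chemokine and adhesion list had medians of 0.11 and 0.53 (the latter above all 10000), with 2 that rose, Vcam1 and Cxcl1 (0.99), and 5 adjusted over the list alone. Matrix genes had medians of 0.03 and 0.45 (the latter above all 10000), with 2 that rose, Col3a1 (0.87) and Vim (0.86), and 6 adjusted over the list alone. Complement and coagulation genes had medians of -0.17, below all but 195, and 0.26, above 9968, and 4 rose in limma (4 rose and 2 fell adjusted over the list alone), with Fgg at 1.36 and Fga from arms of 0.48 and 1.52. Of the antigen presentation genes H2-Aa, a class II chain, rose by 0.86 (limma adjusted p = 0.002), with list medians of 0.16 and 0.36, the latter above 9996, and 2 that rose adjusted over the list alone. Of 3 expressed T and B cell markers Jchain, the joining chain of polymeric immunoglobulins, rose by 1.63 ± 0.20 (limma adjusted p = 4.5e-08), and 2 rose adjusted over the list alone. The cell cycle list had medians of 0.09 and 0.74 (the latter above all 10000), with 0 passing and 5 that rose adjusted over the list alone. The 18S signal given above was highest on the diabetic uninephrectomy array too, where these lists were highest.

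Several epithelial and metabolic lists were lower after uninephrectomy in diabetic mice, though hardly any member passed limma. The proximal tubule median was 0.06 in nondiabetic and -0.35 in diabetic mice, and that of fatty acid oxidation 0.05 and -0.33, both of the latter below all 10000 random lists. In the fatty acid list the ketone body enzyme gene Bdh1 fell by 0.61. The medians of oxidative phosphorylation genes were 0.14, above 9898, and -0.20, below all but 147. The opposite signs of these 3 lists in the 2 arms follow the same split of the arrays as the spike-in probe sets described at the end. Insulin and FOXO targets had medians of -0.11 and -0.21, the latter below all but 42, and Igfbp1, an insulin-repressed binding protein gene, fell by 0.70 (limma adjusted p = 0.012). In nondiabetic mice the antioxidant median was 0.22, above all 10000 random lists, while the osmolyte and glycolysis medians were -0.18 and -0.10, below all but 64 and 234. In diabetic mice the antioxidant, osmolyte and glycolysis medians were -0.07, -0.10 and -0.01, inside the central 95% of random lists. The opposite signs of the antioxidant list follow the split of the spike-in probe sets as well. Podocyte and endothelial medians stayed inside the central 95% of random lists in both comparisons, at -0.02 and -0.05 in nondiabetic and -0.11 and -0.15 in diabetic mice.

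In the single comparisons of uninephrectomy, the highest genes in nondiabetic mice were Lce1h (2.54), Plxnb3 (2.47) and Npy (2.21). The lowest were Adipoq (-3.19, a size that depends on the offset), Hdc, which encodes histidine decarboxylase (-2.80), and Car3 (-2.56). In diabetic mice Lcn2 (3.76), Havcr1 (2.74) and Socs3, a feedback inhibitor of cytokine signalling (2.67), were highest, and Car3 (-2.33), Adipoq (-2.14) and Serpina6 (-1.97) were lowest.

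The effect of uninephrectomy in diabetic mice was set against that in nondiabetic mice, which bears on its use as an accelerating factor. Of the 10 genes with the most positive difference, 4 are on the injury, macrophage or cytokine lists (Lcn2, Havcr1, Cd14 and Vcam1). Lcn2 had a difference of 4.85 on the log2 scale (4.08 to 6.58 under the other offsets, as its nondiabetic signals are near background), Havcr1 3.72, the ubiquitin-like gene Ubd 2.77, Cd14 2.57 and Vcam1 2.56, and all 3 expressed probe sets of Vcam1 were positive. Polr3k (2.71), Dcdc2a (2.66), Alox5ap, needed for leukotriene synthesis (2.63), Smpdl3b (2.54) and Sec24b (2.49) completed the 10. The most negative were Plxnb3 (-3.80), Lce1h (-3.46), 1700128F08Rik (-2.74), Cyp2c65 (-2.52), Npy (-2.49), Adamtsl2 (-2.37), C130026I21Rik (-2.37), Abcg4 (-2.34), Gm3715 (-2.33) and Psg28 (-2.33), each with 1 expressed probe set. The macrophage, tubular injury, matrix, cell cycle and complement lists had median differences of 0.93, 1.05, 0.37, 0.74 and 0.68, all above the 10000 random lists. The fatty acid oxidation median was -0.42, below all of them, and the gluconeogenesis median -0.43, below all but 1.

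In all, 280 genes had a difference of effects of at least 2-fold above 0 and 291 below, against 924 and 1890 without the expression filter. Other expressed probe sets had the same sign for 58 of 74 positive and 38 of 56 negative genes that had any. With both factors in the model this difference has no residual to test it against. With 1 factor left out, whose own effect then lies in the residual, it is the split of the arrays that follows neither factor, and 0 genes passed limma (303 at an unadjusted p below 0.05 with surgery as covariate, and 626 with diabetes). The hybridisation spike-in probe sets, which detect bacterial and phage transcripts added to every sample, followed the same split. All 18 were higher on the nondiabetic uninephrectomy and diabetic sham arrays than on the other 2, by a median of 1.29-fold.

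**Figure D4:**
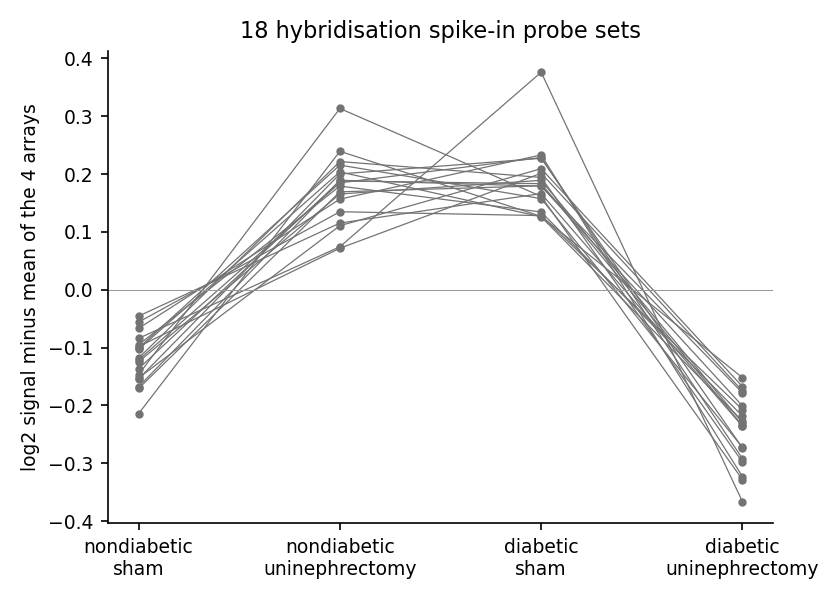
Log2 signal of the 18 hybridisation spike-in probe sets on the 4 arrays (x axis), each set relative to its own mean over the arrays and joined by a line. All 18 are higher on the nondiabetic uninephrectomy and diabetic sham arrays than on the other 2 arrays.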

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

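The spike-in test, the test of proximal tubule share and the test of the nondiabetic sham array were chosen after the result they measure was seen. The rule by which the blood marker test was read was tightened after its value was seen. Bootstrap intervals below resample genes measured on the same single arrays, so they hold no spread between arrays or pools.

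Some genes with the largest difference between the effects of uninephrectomy moved at least 2-fold in opposite directions in diabetic and nondiabetic mice, which drew attention to them. The differences, diabetic minus nondiabetic on the log2 scale, were 4.85 for Lcn2, 2.71 for Polr3k and 2.63 for Alox5ap. They were -3.80 for Plxnb3, -2.74 for 1700128F08Rik, -2.52 for Cyp2c65, -2.37 for C130026I21Rik and -2.33 for Psg28. With both factors in the model the difference was not tested, since each effect is a difference between 2 single arrays, and with 1 factor left out 0 genes passed limma. For Lcn2 the nondiabetic signals of 41.7 and 5.7 both lie below the expression filter, so its lower value there is no sign of a true fall. Polr3k had 4 expressed probe sets, all with the same sign, and the other 7 genes had 1 each.

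A signal also appeared in control probe sets that the comparisons do not use. The 18 hybridisation spike-in probe sets were higher on the nondiabetic uninephrectomy and diabetic sham arrays than on the other 2, by a median of 0.37 on the log2 scale (quartiles 0.32 and 0.41). The 18S ribosomal RNA probe sets were higher on the diabetic uninephrectomy than on the nondiabetic sham array by a median of 1.03 on the log2 scale (1.88-fold as a geometric mean of the 3), a difference for which no explanation was tested.

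The first pattern weighed is the group of 291 genes that were higher on the nondiabetic uninephrectomy and diabetic sham arrays than the 2 factors alone would give. A technical difference between the 2 pairs of arrays would shift the spike-ins too, which carry no kidney RNA, and all 18 did differ between the same pairs, by the median of 0.37. That is a difference between pair means, and a difference of effects is 2 times as large and of opposite sign. Some other array measures followed the same split. The 20th percentile of signal was 30.1 and 29.8 on the nondiabetic uninephrectomy and diabetic sham arrays. It was 23.7 on the nondiabetic sham and 23.3 on the diabetic uninephrectomy array. The 3' to 5' signal ratios of beta-actin (3.49 and 3.72 against 2.78 and 3.38) and Gapdh (0.993 and 1.01 against 0.897 and 0.906) split likewise. The signals of other control probe sets did so only in part. The split separated 14 of 27 labelling controls, 2 of 3 for Gapdh and 3 of 10 other controls. For beta-actin and 18S it separated 0 of 3 each, with median pair differences of -0.22 and -0.30, the other way. For signal specific to single probe sets, the other expressed probe sets of 56 of these genes had a median difference of effects of -0.29 (bootstrap interval -0.41 to -0.11), between the bounds set for either outcome, so this explanation cannot be told apart from a transcript change (on the positive side the median was 0.65, with an interval of 0.45 to 0.79, over 74 genes). A true difference in the effect of uninephrectomy between diabetic and nondiabetic mice stays open as well: it follows the same split of the arrays, and 0 genes passed limma in the fits that leave 1 factor out.

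The second pattern is the higher signal of macrophage and tubular injury genes on the diabetic uninephrectomy array. A lower share of proximal tubule RNA would raise markers of every other cell type alike, but the highest of the podocyte, endothelial and collecting duct medians was 0.017 against 1.23 for macrophage markers (bootstrap interval 0.63 to 1.64). A difference between the pairs of arrays as the whole cause would raise the nondiabetic sham array, of the same pair, by as much, but against the mean of the other pair its medians were -0.14 for macrophage and -0.23 for injury genes, and those of the diabetic uninephrectomy array 1.05 and 1.24 (bootstrap intervals over genes apart in both lists). Blood left in the tissue, although the kidneys were perfused, was not excluded by the markers: the median of 6 blood markers was -0.21, below the bound of 0 set in advance, but 5 of them lay below the expression filter and the bootstrap interval of -0.91 to 0.27 spans 0. The expressed marker, Slc4a1, is also on the collecting duct list, so it does not measure blood alone. The diabetic mice's response to uninephrectomy is the biological explanation the design names, and 1 pool cannot separate it from a single strongly affected mouse.

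The third pattern is the lower signal of adipose genes after uninephrectomy. An array-wide shift left after scaling would lower all genes alike, but the median of all expressed genes was at most 0.019 from 0 in the 2 arms. The adipose medians were -0.65 in nondiabetic and -0.76 in diabetic mice, below all 10000 random lists matched on expression. For this list, these values argue against such a shift as the cause. They decide nothing on a shift before scaling, as the arrays had been scaled to the same trimmed mean. Less fat tissue in the kidney pieces would lower a second list of adipocyte genes too, of which 9 of 20 were expressed, with medians of -0.06 in nondiabetic and -0.47 in diabetic mice. Of 10000 random lists 7563 had a higher median in nondiabetic and 9997 in diabetic mice, so the arms gave different answers. Lpin1, Plin4, Pnpla2, Sncg and Thrsp of that list were lower in both arms. Mgst1 was higher in both, and Dgat2, Gpd1 and Slc2a4 had different signs in the 2 arms. With members that disagree, fat tissue cannot be told apart from a change within the kidney. A response to uninephrectomy itself stays open and untested.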

How the results depend on the processing

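All alternatives were chosen before the data were examined. Of the counts under alternative settings 56 stayed within 1.5 times the value in the report and 47 moved beyond it. Of the values of named genes 5371 stayed, 97 moved and 0 changed sign, and of the list medians 944 stayed, 60 moved and 1 changed sign. That 1 was the osmolyte list with diabetes in uninephrectomised mice, 0.19 in the report and -0.052 under the stricter filter, and the cause was not tested. No replicate could be left out, since each group has 1 array. No paired analysis was possible because each group holds a single array, so the groups share fewer than 2 replicate numbers. Counts are given below in the order diabetes in sham, diabetes in uninephrectomised, uninephrectomy in nondiabetic and uninephrectomy in diabetic mice, then the difference of effects.

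Without the expression filter 1294, 1557, 1242, 1434 and 2814 genes differed at least 2-fold, with 149 for diabetes and 117 for uninephrectomy in both arms, as dim genes are then included. In uninephrectomised mice 657 of them were higher and 900 lower with diabetes, in diabetic mice 577 and 857 with uninephrectomy, and 924 and 1890 for the difference, where the stricter filter gave 83 and 52 and quantile normalisation 297 and 241. Each unfiltered split leaned towards the arrays with the higher 20th percentile of signal. These were nondiabetic uninephrectomy (30.1) and diabetic sham (29.8), against nondiabetic sham (23.7) and diabetic uninephrectomy (23.3). Whether array background set these splits was not tested. With the stricter filter, which leaves fewer genes, the counts were 34, 119, 24, 60 and 135, and 6 and 4 in both arms. Probe sets counted singly gave 251, 537, 270, 373 and 1073, and 22 for uninephrectomy in both arms, from more probe sets. A threshold of 1.5-fold, lower by construction, gave 839, 1399, 747, 1049 and 2065, and 197 and 84 in both arms. An offset of 1, which widens the differences of dim genes, gave 226 for diabetes in sham mice, 206 for uninephrectomy in nondiabetic mice and 34 for diabetes in both arms. The offset at the 40th percentile, which narrows them, gave 73 for diabetes in sham mice, 63 and 147 for uninephrectomy and 349 for the difference, and 9 in both arms for each factor.

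Genes passing limma for diabetes were 13 without the filter, 5 with the mean of probe sets, 62 with probe sets singly and 0 without a trend. For uninephrectomy they were 2, 2, 16 and 4, with 115 after quantile normalisation, 104 after median centring and 90 at an adjusted p below 0.1. The cause was not tested, apart from the wider threshold. Under the other settings the diabetes count stayed between 226 and 311, and the contrast that follows neither factor gave 0 under every setting. Of the 21 genes 2-fold different with diabetes in both arms, 20 were found after either scaling, and of the 14 for uninephrectomy 12 and 14. Quantile normalisation changed the split for uninephrectomy in nondiabetic mice to 63 higher and 72 lower. Signals near background limit what can be said of dim genes.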

Other observations

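Circadian clock genes were lower on the diabetic uninephrectomy array. Of 15 expressed members 12 were lower with diabetes in uninephrectomised mice (median -0.24, below all but 116 random lists) and 12 after uninephrectomy in diabetic mice (-0.30, below all but 9), while the sham and nondiabetic medians were both 0.06. The opposite signs in the 2 arms follow the same split of the arrays as the spike-in probe sets. The median difference of effects was -0.32, below all but 79 random lists. The output gene Dbp fell after uninephrectomy by 0.69 (SE 0.15, limma adjusted p = 0.01), with -0.68 in nondiabetic and -0.71 in diabetic mice. Bhlhe40, a clock repressor gene, fell with diabetes by 0.54 (limma adjusted p = 0.037). These were the only members to pass, also adjusted over the list alone.

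Immediate early genes other than Egr1 moved apart. Dusp1, a phosphatase gene named here after its values were seen, fell with diabetes by 0.56 (limma adjusted p = 0.028). Over 17 expressed immediate early and heat shock genes 0 rose and 2 fell in limma, while 4 rose and 5 fell adjusted over the list alone. The list median was 0.16 with diabetes in uninephrectomised mice and 0.15 after uninephrectomy in diabetic mice, above 9814 and 9795 random lists, and -0.08 and 0.01 in the other arms. Myc, a growth regulator, had signals of 129.2 and 245.7 in nondiabetic and of 214.0 and 553.7 in diabetic sham and uninephrectomised mice, with no pass for either factor. Atf3 was at 459.5 on the diabetic uninephrectomy array and between 115.6 and 151.4 on the others. The endoplasmic reticulum stress list had medians of -0.17 with diabetes in sham mice, below all but 25 random lists, and of 0.17 after uninephrectomy in diabetic mice, above 9946, and 0 of its 17 members passed by either adjustment. Of 7 sex-linked and sex-biased genes Cyp4a12a rose with diabetes and Abcc3 fell after uninephrectomy, and the list medians lay inside the central 95% of random lists.

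Adrenal, skeletal muscle and blood lists had 1 expressed member each, Star, Ckm and Slc4a1 (the last also on the collecting duct list), and 0 passed over all genes. The beta-actin ratio of 3' to 5' signal, a measure of RNA integrity, was 2.78, 3.49, 3.72 and 3.38 in nondiabetic sham, nondiabetic uninephrectomy, diabetic sham and diabetic uninephrectomy mice, and that of Gapdh 0.897, 0.993, 1.01 and 0.906. Both ratios were higher on the nondiabetic uninephrectomy and diabetic sham arrays, the split of the spike-in probe sets.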
